A study of Danio rerio with 2 samples.

How the data were processed

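Whole zebrafish larvae of 2 treatments, DMSO and BaP, were profiled by stranded mRNA sequencing, with 1 library per treatment. Per the labels' protocols, total RNA came from 4 pooled biological replicates, and 200 ng entered the preparation of each library. Trimmomatic 0.38, STAR 2.6.1d, featureCounts 1.6.3 and the builds danRer11 and GRCz11 are named in the submitters' processing notes, with no role or order. The file gives Ensembl gene coordinates and does not itself name a build. How reads that map to several genes were treated, and whether counting used the strand, is not given in the sources used here.

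The deposited values are whole numbers, but they are a score scaled by the authors and not raw counts: low values alternate in frequency in a way that whole reads multiplied by a constant and rounded would give. The scaling method and any filter on genes are not given in the sources used here. The factor of each library was estimated from that pattern by maximum likelihood as 0.679 (DMSO) and 0.544 (BaP), with margins of 178 and 293 log-likelihood units over the next candidate factor. Dividing by it gave estimated reads, about 19806000 and 21997000 in all. Because of the rounding, reads are known only to within about 1 read, so the intervals were widened for it. On simulated data the factor was recovered within 0.001 for 8 of 8 scaled columns, but for 0 of 2 unscaled columns, in which 0.5004 was the largest error. The estimate therefore presumes that the columns were scaled. Taking the values themselves as reads gave 619 higher and 590 lower genes.

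The analysis had been planned for raw counts. With normalized values the main result became the ratio of the deposited values, BaP over DMSO, as the plan provided. The plan allowed intervals only if whole reads could be recovered. They were recovered only approximately, and intervals are nonetheless given, as approximate. Genes with a sum of at least 10 over both libraries entered. A gene was apart when its fold was at least 2 and the two-sided exact binomial test on the estimated reads had a Benjamini-Hochberg adjusted p under 0.05. Intervals are Clopper-Pearson intervals at 95%, conditional on the sum of the reads. In the ratio a 0 was set to 3 reads, while the interval and the test took it as 0. Intervals cover counting error only. Reads carry no molecular identifiers, so copies of 1 molecule count as separate reads, and the intervals may be too narrow even for counting error. On data simulated for this comparison, with 50 genes per fold, the rule called 2% of genes changed 1.5-fold, 96% of those changed 3-fold, 94% at 4-fold and 98% at 8-fold, and 1 of 21502 unchanged genes. Of the intervals, 96.3% held the true ratio. The simulation holds no variation between animals.

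Fixed before the data were examined were 50 gene lists, 39 of them lists of symbols and 11 defined by symbol patterns. Of 1510 listed symbols 1398 were matched, 41 of them through another symbol in the name table. Symbols that a pattern took in without belonging to the family were removed after the symbols, not the values, had been seen. For each list with at least 3 measured genes, the median log2 ratio was placed among 10000 random lists of the same size, matched in 20 expression bins, and called outside the range when it fell in the outer 0.5% at either end. Members were drawn with replacement within a bin. Of 200 simulated lists of unchanged genes, 0% fell outside.

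The genes named are the 12 higher and 12 lower genes whose interval lay farthest from equality, leaving out clone names, then up to 4 such members of each list, or the 2 most abundant members where none was apart, and every AhR target and AhR receptor gene. This rule was fixed before the data were examined. The partner genes of the receptor, the other members of groups of 5 or fewer and some genes that were not apart were named too, beyond the rule, after their values had been seen. A gene that the rule selects is not reported here. Alternatives were other scalings, filters, folds and trend corrections. The assumed coefficients of variation, the pseudocounts and the use of values as reads were chosen after the data had been seen. Scaling by trimmed mean of M values had been planned as the main scaling for raw counts. Its use as an alternative on the normalized values was added after the data had been seen. Count models were not used, because the values are not counts, and the planned tests with an assumed variation were replaced by a normal approximation. A correction for GC content was not made, since no genome was used here. Terms of pathways and gene ontology in the table, with 15 to 500 measured genes, were described as exploratory. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.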

Results

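RNA was sequenced from whole wild-type zebrafish larvae of the AB strain at 6 days post fertilization (dpf). The larvae had spent the interval between 3 and 6 dpf in benzo[a]pyrene (BaP, 1 µM) or in the solvent dimethyl sulfoxide (DMSO, 0.1%). BaP is a polycyclic aromatic hydrocarbon formed by incomplete combustion and a ligand of the aryl hydrocarbon receptor (AhR), a transcription factor that induces xenobiotic-metabolizing enzymes. Each treatment was represented by 1 library, prepared from RNA of 4 pooled biological replicates. The deposited table gave a normalized read count, rounded to a whole number, for 22849 genes in each library. These values summed to 13443263 in the DMSO library and 11968060 in the BaP library, and corresponded to about 19806000 and 21997000 estimated reads. The median value was 143 in both libraries. The 100 most abundant genes held 28.5% of the DMSO values and 24.8% of the BaP values, and genes of the mitochondrial genome held 5.19% and 7.1%.

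The study concerns BaP toxicity to bone, and the comparison asks which transcripts differed between larvae kept in BaP and in DMSO. The median ratio of the AhR target, oxidative stress, heat shock and erythrocyte gene lists was higher than in random lists, and that of the collagen, cartilage, exocrine pancreas, liver and keratin lists was lower. Of 21764 genes with enough reads to be compared, 709 were higher and 756 lower in the BaP library by at least 2-fold. A difference of at least 4-fold was found for 168 higher and 98 lower genes, and of at least 8-fold for 56 and 20. The cytochrome P450 gene cyp1a, whose product oxidizes BaP, had a normalized read count of 650 in the DMSO library and 17859 in the BaP library, a 27.5-fold difference (95% interval 25.7 to 29.3).

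A gene was counted when its fold was at least 2 and a two-sided exact binomial test on the estimated reads passed a Benjamini-Hochberg adjusted threshold of 0.05. This test compares these 2 libraries, not the treatments, because with 1 library per treatment the difference has no replicate check, and the intervals cover counting error only. For 25 of the counted genes the interval included no difference. When the libraries were scaled by the total of all values, which moved every log2 ratio by 0.17, the split became 1009 higher and 508 lower. With the trend of the ratio on expression removed it was 826 and 587. Higher genes also outnumbered lower ones under the median of ratios (788 and 640) and the trimmed mean of M values (801 and 633). Which direction held more genes thus depended on the scaling. If libraries of the same treatment were assumed to vary with a coefficient of variation of 0.4, 25 genes were higher and 2 lower.

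Besides cyp1a, the genes that lay farthest above equality in the BaP library included eevs (Ensembl gene ENSDARG00000087873, chromosome 6, 43438074 to 43449013), with 21 normalized reads in the DMSO library and 930 in the BaP library (44.3-fold, 95% interval 30.5 to 67.4). The gene eevs encodes an enzyme of the synthesis of gadusol, a sunscreen compound of fish. Of the heme-binding protein family, soul5 was 20.2-fold higher and hebp2 18.0-fold higher. The cytochrome P450 gene cyp1b1 was 22.8-fold higher, wdr76 24.1-fold, crtac1a 17.3-fold and prdx1, which encodes a peroxiredoxin, 15.7-fold. The prostaglandin D synthase gene ptgdsb.1 reached 69229 normalized reads against 4390 in the DMSO library, 15.8-fold higher, and fam213b was 15.2-fold higher. The matrix metalloproteinase gene mmp13a (ENSDARG00000114451) was 16.0-fold higher, with 51 and 814 normalized reads. The yolk precursor gene vtg7 had 1 and 97 normalized reads, so that its ratio of 97.0 has a wide interval, from 18.5 to 24230.

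The genes farthest below equality included ahsg2 (ENSDARG00000069293, chromosome 2, 10134345 to 10141741), which encodes the plasma protein fetuin and had 544 normalized reads in the DMSO library and 33 in the BaP library (16.5-fold lower, 95% interval 12.5 to 22.2). Its relative ahsg1 was 6.29-fold lower. The keratin genes krtt1c19e and cyt1l were 7.60-fold and 5.89-fold lower, and chia.3, a chitinase gene, was 8.59-fold lower. The apolipoprotein E gene apoea was 4.88-fold lower, with 2306 and 473 normalized reads. Of the cytochrome P450 family 2, cyp2ad2 was 7.17-fold lower, cyp2aa8 12.8-fold lower, and both gene models named cyp2x12 were lower, with 40 and 1 and with 43 and 4 normalized reads. The antigen presentation gene cd74a had 44 and 3 normalized reads, and hpx, for the heme scavenger hemopexin, had 33 and 3.

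AhR targets checked the labels of the libraries. Of 10 measured targets 6 were higher and 0 lower in the BaP library, and the median log2 ratio of 2.14 lay above all 10000 random lists matched on expression. Besides cyp1a and cyp1b1, the gene model CABZ01114318.1, which the name table pairs with the AhR repressor gene ahrra, was 11.6-fold higher, and its copy ahrrb 8.60-fold higher. The gene cyp1c2 was 7.99-fold higher and the forkhead gene foxq1a 2.45-fold higher. The other targets differed by less than 2-fold, with normalized reads of 2048 and 3389 for sult6b1, 488 and 722 for tiparp, 775 and 1100 for nqo1, and 107 and 86 for foxf2a. No member of the list of the receptor and its partners was apart among 8 measured (median log2 ratio -0.02, percentile 69.9 of the random lists). The receptor genes had 2342 and 2934 normalized reads for ahr2, 373 and 375 for ahr1b, and 31 and 34 for ahr1a. The partners had 369 and 347 for arnt, 2053 and 1684 for arnt2, 774 and 750 for aip, 67235 and 59336 for hsp90ab1, and 194 and 283 for ptges3b.

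**Figure D1:**
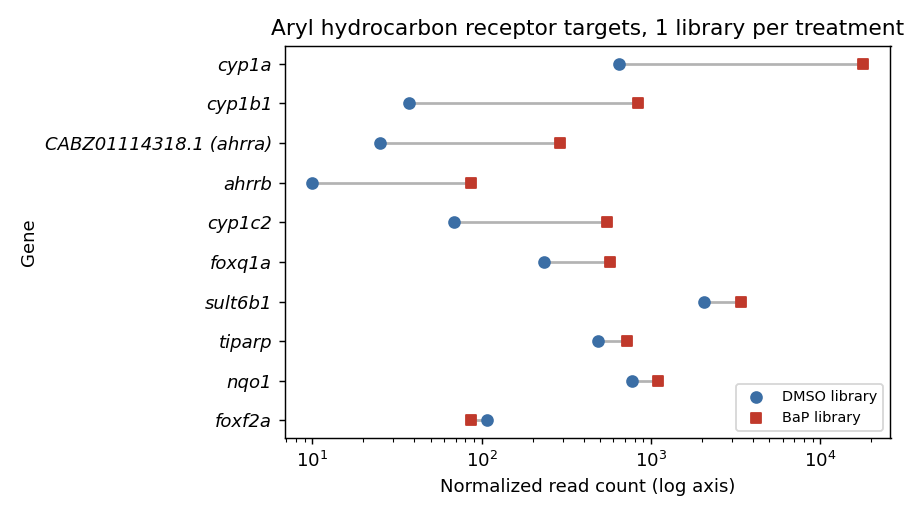
Normalized read counts of the 10 measured AhR target genes in the DMSO library (circles) and the BaP library (squares), on a log axis, with 1 library per treatment. The counts for cyp1a went from 650 to 17859, and foxf2a, with 107 and 86, was the only target with a lower count in the BaP library.

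Conjugation genes differed in both directions, and the efflux and antioxidant lists had medians above the range of random lists. Of 41 glutathione and glucuronide conjugation genes 8 were higher and 5 lower (median log2 ratio 0.06, percentile 96.4, inside the range of random lists). The members farthest from equality were the glutathione transferase genes gstp2 (9.63-fold), gstp1 (5.54-fold) and gsto2 (3.71-fold) and the glucuronosyltransferase gene ugt5a1 (9.23-fold), all higher. The 5 lower members, named after their values had been seen, had 256 and 82 normalized reads for gsta.2, 499 and 244 for GSTZ1, 41 and 15 for ugt1b2, 45 and 22 for ugt1b7, and 15 and 5 for sult3st1. Of 13 ABC efflux transporter genes 3 were higher and 0 lower (median 0.45, percentile 99.99), namely abcg2b (8.06-fold), abcg2a (2.86-fold) and abcc4 (2.88-fold). Of 32 oxidative stress and Nrf2 target genes 10 were higher and 1 lower (median 0.71, above all random lists). The lower gene, named after its values had been seen, was the heme oxygenase gene hmox1a, with 505 and 178 normalized reads. After prdx1, the members farthest from equality were txn, encoding thioredoxin (4.48-fold), nfe2l2b, an Nrf2 gene (4.66-fold), and the cystine transporter gene slc7a11 (4.27-fold), all higher. Of 43 genes of cytochrome P450 families 2 and 3, 2 were higher and 11 lower (median -0.54, below all random lists). This list shares members such as cyp2ad2 with the liver list, whose median was also below all random lists, so these are not separate results.

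Heat shock genes included the most higher members among the stress lists. Of 43 heat shock and unfolded protein genes 17 were higher and 0 lower (median 0.65, above all random lists). The inducible chaperone genes rested on few reads in the DMSO library, with normalized reads of 3 and 55 for hsp70.2, 1 and 30 for hsp70.1, 8 and 75 for hsp70l, and 6 and 50 for hsp70.3. Of 34 p53 and DNA damage response genes 3 were higher and 0 lower (median 0.25, above all random lists): the ribonucleotide reductase gene rrm2b (3.27-fold), the caspase gene casp3b (2.99-fold) and gadd45aa (2.56-fold). The other 31 were not apart, and over the whole list 25 lay above a ratio of 1 and 9 below. Of 31 nucleotide excision repair genes 1 was higher, the damage recognition gene xpc (4.61-fold), and 0 lower (median 0.09, percentile 97.4, inside the range of random lists). Of 28 hypoxia response genes 8 were higher and 0 lower (median 0.33, above all random lists), among them egln3, a prolyl hydroxylase gene (4.96-fold), ankrd37 (3.47-fold), the hexokinase gene hk2 (2.86-fold) and the glucose transporter gene slc2a1b (2.53-fold). Of 20 glucocorticoid and stress axis genes 4 were higher and 0 lower (median 0.30, percentile 99.98): fkbp5, a receptor co-chaperone gene (5.58-fold), per1a (2.44-fold), the gluconeogenesis gene pck1 (2.08-fold) and cebpb (2.04-fold). Of 35 circadian clock genes 7 were higher and 0 lower (median 0.21, percentile 99.99), including cry5 (13.6-fold), cry-dash (6.63-fold), nfil3-6 (5.31-fold) and tefa (3.97-fold). The genes cry5 and cry-dash belong to the photolyase and cryptochrome family.

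Of the skeletal groups, the cartilage and osteoblast lists had medians below all random lists, and 5 genes of the osteoclast list were higher. Of 42 chondrocyte and cartilage genes 0 were higher and 16 lower (median -0.79, below all random lists), led by the cartilage collagen genes col11a1a (2.72-fold lower, 95% interval 2.61 to 2.83), col9a3 (2.58-fold lower), col11a2 (2.49-fold lower) and col2a1a (2.42-fold lower, 11776 and 4860 normalized reads). Of 56 osteoblast and mineralization genes 3 were higher and 16 lower (median -0.41, below all random lists). One of the 3, col10a1b, named after its values had been seen, had 2 and 8 normalized reads and an interval that included no difference. The lower members included col10a1a, a collagen gene of maturing bone and cartilage cells (3.79-fold), scpp1, a secretory calcium-binding phosphoprotein gene (4.35-fold), and ucmaa, a cartilage matrix gene (5.38-fold, with 43 and 8 normalized reads). The gene tnfrsf11b (ENSDARG00000098377), which encodes osteoprotegerin, a decoy receptor for the osteoclast factor RANKL, was 8.26-fold higher (95% interval 6.43 to 10.8), with 50 and 413 normalized reads.

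Of 41 osteoclast genes 5 were higher and 0 lower (median 0.12, percentile 99.6), 36 were not apart, and over the whole list 25 lay above a ratio of 1 and 13 below. With the trend on expression removed the median was 0.16 and the percentile 99.2, inside the range of random lists. Besides mmp13a, the members farthest from equality were fosl1a, an AP-1 transcription factor gene (70 and 720 normalized reads), the gelatinase gene mmp9 (6.84-fold) and csf1b, for a macrophage growth factor (3.54-fold). Members that were not apart, picked out after their values had been seen, included ctsk (569 and 642 normalized reads), acp5a (26 and 32), tcirg1a (705 and 628), the RANKL gene tnfsf11 (21 and 21) and its receptor gene tnfrsf11a (251 and 220). The neutrophil and macrophage list, which also holds mmp9, mmp13a and some lymphocyte genes, had 7 higher and 5 lower of 46 genes (median 0.10, percentile 99.3). In it cyba, for an NADPH oxidase subunit, was 2.80-fold higher. The 5 lower genes were the antigen presentation genes cd74a and cd74b and the lymphocyte genes rag1, rag2 and lck, all but cd74a named after their values had been seen. Of 21 matrix metalloproteinase genes 3 were higher and 2 lower (median -0.26, percentile 2.38). A second gene model named mmp13a (ENSDARG00000012395) was 3.36-fold higher, and mmp30 was 2.37-fold lower.

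Of 54 collagen genes 1 was higher, col10a1b, and 24 lower (median -0.93, below all random lists), with col14a1b 4.51-fold, col7a1 4.43-fold and col5a3b 4.09-fold lower. The collagen list shares genes with the cartilage and osteoblast lists, col10a1a among them. Of 50 collagen processing and matrix turnover genes 4 were higher and 7 lower (median -0.41, below all random lists). In this list the proteoglycan gene lum (2.94-fold) and the fibronectin gene fn1b (2.22-fold) were lower, and the prolyl hydroxylase gene p3h1 (3.04-fold) and the lysyl oxidase gene loxl2a (2.91-fold) were higher. Of 33 calcium, phosphate and vitamin D genes 2 were higher and 2 lower (median -0.19, percentile 5.15). The phosphate transporter gene slc20a1b was 2.11-fold higher, the parathyroid hormone gene pth1a had 3 and 24 normalized reads, the phosphate hormone gene fgf23 had 33 and 12, and the calcium-binding gene pvalb1 was 2.07-fold lower. Of 38 Wnt signalling genes 1 was higher and 5 lower (median -0.34, below all random lists), with the secreted inhibitor genes sfrp2 (2.53-fold), sfrp5 (2.06-fold) and dkk1b (48 and 24 normalized reads) and the inhibitor gene nkd2a (2.38-fold) lower. The remaining lower gene was the ligand gene wnt10b (25 and 11 normalized reads) and the higher gene the ligand gene wnt5a (15 and 31), both named after their values had been seen. Other inhibitor genes, picked out likewise, were not apart, with log2 ratios of -0.50 for wif1, -0.29 for dkk3b and -0.14 for sfrp1b. Of 34 retinoic acid genes 0 were higher and 3 lower (median -0.26, percentile 0.13; 0.6 for the mean, inside the range), namely rbp2a (3.42-fold), lrata (2.22-fold) and the receptor gene rargb (2.19-fold).

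**Figure D2:**
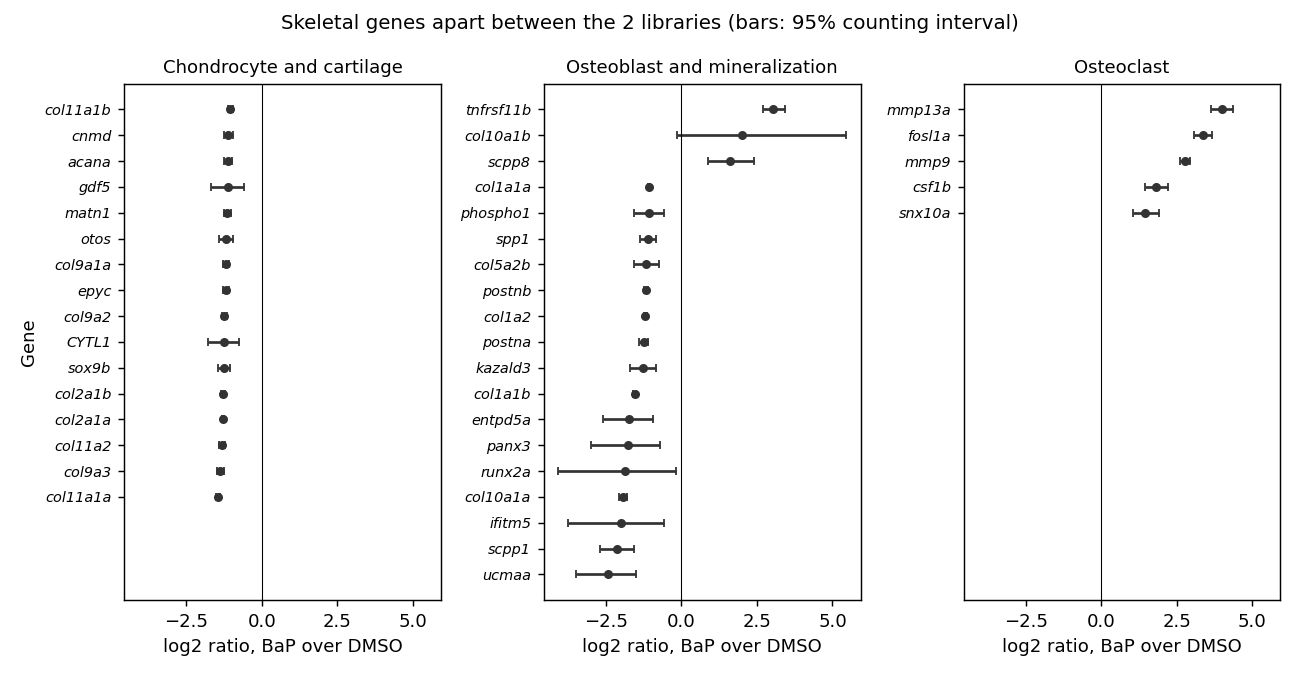
Log2 ratio of the BaP over the DMSO library for the members of 3 skeletal gene lists that were apart, with bars for the 95% counting interval and 1 library per treatment. Of these selected members, the 16 cartilage genes lie below 0 and the 5 osteoclast genes above it, and of the osteoblast and mineralization genes 3 lie above and 16 below. The 36 osteoclast genes that were not apart are not drawn.

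The lists of digestive organs had medians below all random lists. Of 28 exocrine pancreas genes 0 were higher and 19 lower (median -1.23, below all random lists), including the trypsin gene prss59.1 (3.53-fold), the carboxypeptidase genes cpb1 (3.42-fold) and cpa4 (3.31-fold) and the elastase gene ela3l (3.26-fold). The list held 2.79% of the DMSO values and 1.29% of the BaP values. Of 37 liver genes 1 was higher and 14 lower (median -0.86, below all random lists), with ahsg2, cyp2ad2, ahsg1 and hpx farthest from equality. Of 43 intestine genes 2 were higher and 6 lower (median -0.41, below all random lists), the lower members including chia.3, rbp2a, the keratin gene krt92 (2.96-fold) and the fatty acid-binding protein gene fabp1b.1 (2.99-fold).

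The keratin and skeletal muscle lists also had medians below all random lists. Of 16 keratin genes 1 was higher and 9 lower (median -1.25, below all random lists), with krt4 3.53-fold lower (71631 and 20308 normalized reads) and krt15 3.52-fold lower. Of 44 epidermis and keratinocyte genes, a list that shares keratins with the former, 2 were higher and 9 lower (median -0.27, percentile 0.1), and 20 had a ratio above 1. Of 40 skeletal muscle genes 0 were higher and 6 lower (median -0.63, below all random lists), including the actin gene acta1b (2.58-fold), the parvalbumin gene pvalb3 (3.65-fold) and the myosin-binding protein gene mybpc2b (2.28-fold). Of 16 cardiomyocyte genes none was apart (median -0.27, percentile 2.94, inside the range), and myh7l had 721 and 686 and myl7 359 and 267 normalized reads.

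Erythrocyte genes were higher, with 17 of 27 higher and 0 lower (median 1.15, above all random lists). The mitochondrial transport gene tspo was 8.88-fold higher, the heme synthesis genes alas2 and urod 5.58-fold and 3.07-fold higher, and slc4a1a, for the red cell anion exchanger, 4.03-fold higher. All 8 measured hemoglobin genes were higher (median 1.34, above all random lists), among them hbae3 (2.54-fold), hbbe1.1 (2.46-fold), hbae1 (2.90-fold) and hbbe1.2 (2.32-fold). Some of these genes, such as hbae3, are also on the erythrocyte list. Of 51 inflammation and acute phase genes 8 were higher and 6 lower (median 0.00, percentile 89.4). The interleukin gene il11a had 1 and 25 normalized reads, irg1l had 138 and 566, and the antiviral gene rsad2 had 21 and 2.

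Of 52 photoreceptor and retina genes 0 were higher and 1 lower, the green opsin gene opn1mw1 (2.21-fold), with a median of -0.40 below all random lists. Of 30 lens genes 1 was lower, cryba1a with 10 and 2 normalized reads (median 0.09, percentile 96.7), and of 20 gamma crystallin M2d genes none was apart (median -0.26, percentile 0.12; 1.92 against unmatched lists and 0.74 for the mean, both inside the range), with 1496 and 1175 for crygm2d8 and 1268 and 974 for crygm2d10. Of 50 neuron and glia genes 1 was lower, the glial filament gene gfap (2.13-fold), and 0 higher (median -0.14, percentile 7.48). Of 31 pigment cell genes 1 was higher, aox5 (2.26-fold), and 3 lower (median -0.54, below all random lists): the melanosome gene pmelb (2.23-fold), the tyrosinase gene tyr (2.03-fold) and the pteridine synthesis gene pts (2.31-fold). Of 39 endothelium genes, a list that includes mural cell genes, 2 were lower (median -0.11, percentile 16.2), the smooth muscle genes tagln (2.46-fold) and acta2 (2615 and 1190 normalized reads). Of 48 kidney and ionocyte genes 3 were higher and 3 lower (median -0.18, percentile 2.15), with the ammonia transporter gene rhcgl1 (4.16-fold), the sodium-chloride cotransporter gene slc12a3 (2.88-fold) and the sodium-proton exchanger gene slc9a3.1 (2.73-fold) higher and the carbonic anhydrase gene ca15a (485 and 194 normalized reads) lower.

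Of 34 glycolysis and gluconeogenesis genes 2 were higher and 8 lower (median -0.30, percentile 0.25; 0.6 for the mean and 0.5 with a minimum sum of 50, no longer outside the range), with the pyruvate kinase genes pklr (3.36-fold) and pkmb (3.34-fold) lower. Of 55 fatty acid and lipid genes 3 were higher and 8 lower (median 0.00, percentile 95.1), with apoea and cyp4v8 (3.22-fold) lower and the desaturase gene scd (9 and 59 normalized reads) and the leptin gene lepb (2 and 29) higher. Of 25 cholesterol and sterol synthesis genes 1 was higher, sqlea with 5 and 15 normalized reads (median 0.20, percentile 99.6), and the percentile was 99.3 after thinning and 96.0 for the mean, both inside the range. Of 20 estrogen and gonadal steroid genes 2 were higher and 1 lower (median 0.32, percentile 99.9). These were vtg7, amh with 3 and 10 normalized reads and an interval that included no difference, and the steroid synthesis gene cyp17a1 (2.13-fold lower). With a minimum sum of 50 the percentile of this list was 78.3. Of the 2 measured vitellogenin genes, 1 was higher. Of 16 thyroid axis genes 2 were higher and 3 lower (median -0.13, percentile 30.3), with the thyroglobulin gene tg (2.58-fold), the thyroid hormone carrier gene ttr (2.15-fold) and the gene model si:ch211-286f9.2, which the name table pairs with iyd (2.84-fold), lower and the deiodinase gene dio1 (2.12-fold) higher.

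Of 48 cell cycle genes 0 were higher and 1 lower, e2f1 with 26 and 13 normalized reads (median -0.33, below all random lists; percentile 0.51 for the mean, inside the range). Of 79 ribosomal protein genes 1 was higher, rpl37 (2.54-fold), and 0 lower, while 75 had a ratio below 1 (median -0.47, below all random lists). Of 86 nuclear respiratory chain genes 3 were higher and 0 lower (median 0.05, percentile 99.94), but against unmatched lists and for the mean (98.9) the list was no longer outside the range. The higher genes were sdha (2.96-fold) and sdhb (2.90-fold), for succinate dehydrogenase, and ndufv1 (2.53-fold). Of the 13 genes encoded in mitochondria none was apart (median 0.29, percentile 99.96; 99.49 against unmatched lists and 98.1 for the mean, both inside the range), and mt-co1 had 266934 and 354490 and mt-co2 105691 and 122886 normalized reads. With the trend on expression removed mt-co1 became apart, its log2 ratio moving from 0.41 to 1.25. Of 14 histone genes none was apart (median -0.16, percentile 25.0), with 7955 and 7719 for h1f0 and 5981 and 4694 for h3f3c.

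The naming rule left out some members of groups of 5 or fewer, which are given here after their values had been seen, by normalized reads in the DMSO and the BaP library. Higher genes were cyp2x7 (59 and 227) and cyp2x6 (1 and 11) of the cytochrome P450 families, scpp8 (16 and 49) of the osteoblast list, snx10a (45 and 124) of the osteoclast list, and loxa (162 and 376) and timp2b (84 and 193) of the matrix turnover list. Others were krt95 (1 and 9) of the keratins, cldnb (713 and 1516) and tgm1l4 (15 and 38) of the epidermis list, agr2 (141 and 315) and anpepb (2048 and 4497) of the intestine list, pah (2504 and 5655) of the liver list, acadvl (2537 and 5091) of the lipid list and CT573065.1 (143 and 292) of the thyroid list. Lower genes were mmp11b (41 and 12) of the metalloproteinases, and atp1a1a.2 (2034 and 910) and wt1b (29 and 13) of the kidney list. In the neutrophil and macrophage list, cd74b (42 and 18) and the lymphocyte genes rag1 (236 and 89), rag2 (18 and 7) and lck (31 and 14) were lower. Apart from the partners of the receptor, the genes named beyond the rule were not run one by one under the alternatives.

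**Figure D3:**
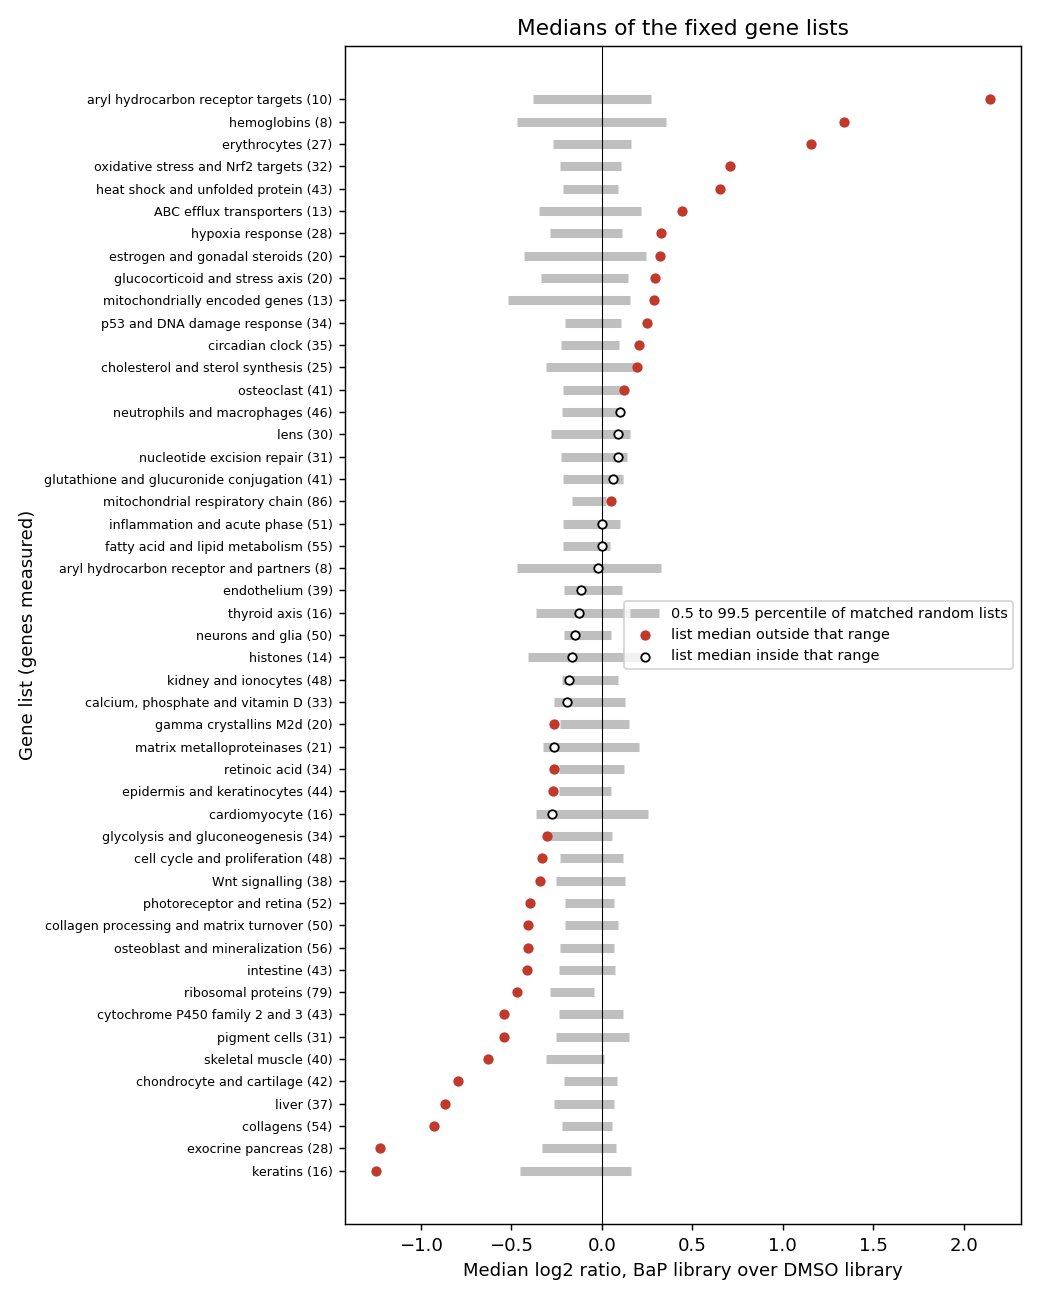
Median log2 ratio of the BaP over the DMSO library for the 49 gene lists with at least 3 measured genes, with grey bars for the range of 10000 random lists without the outer 0.5% at each end. Filled points lie outside that range, 15 above and 19 below, from the AhR targets at 2.14 to the keratins at -1.25.

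Of the 49 lists 34 lay outside the range of random lists, 15 above and 19 below, where 0.49 would by chance if the genes of a list were independent, which genes of a tissue are not. Some lists also share genes, such as collagens with cartilage and osteoblasts and hemoglobins with erythrocytes, so they are not separate results. Of 143 genes selected by the naming rule that were apart, 16 came within 2-fold or lost the test under another scaling, thinning or trend removal: acta2, amh, col2a1a, cyp17a1, dkk1b, e2f1, fn1b, gfap, lrata, opn1mw1, pmelb, pvalb1, rargb, sfrp5, ttr and tyr. The other alternatives, among them the assumed coefficients of variation, were not run on named genes one by one. A coefficient of variation of 0.4 left 25 higher and 2 lower genes in the whole comparison, so most of the 143 calls would end under it. Near-identical copies, such as the hemoglobin, hsp70, gamma crystallin, keratin, mmp13a and cyp2x12 genes, may share reads, so their single values are uncertain.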

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

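The assumed coefficients of variation, the pseudocounts and the values taken as reads were chosen after the data had been seen. So was the use of the trimmed mean of M values as an alternative, a scaling that had been planned for raw counts. Of 18 alternatives, 14 left the count of higher genes within 1.5 times 709 and 13 left that of lower genes within 1.5 times 756. Among these, upper quartile scaling removed a log2 shift of 0.0, so its counts of 709 and 756 could not differ from the main result. A minimum sum of 50, which leaves fewer genes to compare, left 497 lower genes, a fold of 1.5 gave 1559 higher and 1843 lower, and intervals wholly beyond 2-fold left 362 and 283. An assumed coefficient of variation of 0.2 left 289 and 168, and of 0.4 left 25 and 2. Scaling by the total gave 1009 and 508, 66.5% higher against 48.4%, and removal of the expression trend 826 and 587, or 58.5%. The median of ratios gave 788 and 640, and the total without the 1% most abundant genes 778 and 650. The trimmed mean of M values gave 801 and 633, and removal of the trend on genomic span 794 and 648. In the main result the median log2 ratio of measured genes was -0.06, and 56.35% of them had a negative ratio. No list that lay outside the range reversed. No named gene that was apart reversed either, but under scaling or trend removal none could. These changes moved log2 ratios by at most 0.17 and 0.84, less than the 2-fold threshold. List medians that left the outside range were: with a sum of at least 50, estrogen (0.024) and glycolysis (-0.30); thinned, cholesterol (0.16); with the expression trend removed, osteoclast (0.16); by means, retinoic acid (-0.26), cholesterol (0.17), glycolysis (-0.33), cell cycle (-0.26), mitochondrially encoded (0.30), respiratory chain (0.10) and gamma crystallins (-0.25); against unmatched lists, mitochondrially encoded (0.29), respiratory chain (0.053) and gamma crystallins (-0.26). Neutrophils and macrophages entered it without a filter (0.15), with a sum of 50 (0.21), and with the expression (0.18) or span (0.17) trend removed. The cause was not tested. Planned count-model tests were not run. Thinning ended the calls of amh, with 3 and 10 normalized reads and an interval from 0.976 to 18.2-fold, and of e2f1 (-0.97), which lay at the 2-fold threshold and lost its call under other scalings as well.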

Other observations

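All tests of explanations here were chosen after the results had been seen, and the terms below are exploratory. Of 136 pathways in the table's annotation, which covers 22.3% of the measured genes, 11 lay above and 13 below the range of random lists, where 1.36 in all would by chance. Porphyrin and chlorophyll metabolism, a term not confined to heme synthesis, had 9 of 25 genes higher and 1 lower (median log2 ratio 0.47). Glutathione metabolism had 16 of 47 higher and 1 lower (0.30). The 46 proteasome genes had a median of 0.38 with none apart, and the 70 genes of ribosome biogenesis 0.17 with none apart, while the 122 ribosome genes had -0.40. Extracellular matrix receptor interaction had 14 of 73 genes lower and 1 higher (-0.45). Of 2206 gene ontology terms 147 lay above and 213 below, where 22.06 in all would by chance, and many terms share genes. The term for regulation of ossification had 4 of 15 genes lower and 0 higher (-0.51), and that for protein targeting to mitochondrion 2 of 18 higher and 0 lower (0.47).

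The circadian list had a median log2 ratio of 0.21, with 23 of its 35 genes above a ratio of 1 and 7 apart, all higher. A difference in the time of day at sampling could move clock genes in both directions, and 7 higher with 0 lower leaves this open, because sampling times are not given in the sources used here. Light before sampling is open too. Of light-responsive genes, singled out after their values were seen, cry1aa, outside the list, had a log2 ratio of 0.49, below 2-fold, while per2 (1.18), cry-dash (2.73) and cry5 (3.76) of the list were apart. Neither can be told apart from BaP itself with 1 library per treatment.

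The exocrine pancreas and liver lists had medians below all random lists. A trend of the ratio with abundance is argued against as the whole cause, since the medians with that trend removed were -0.89 and -0.65, still below the range of random lists. A smaller share of pancreas RNA in the BaP library may account for part of the pancreas list, with 28 of 28 genes below a ratio of 1, but lower expression per cell would give the same. Share alone would move the members alike only if all their RNA came from the pancreas, which was not measured. The log2 ratios of the members ran from -1.818 to -0.06, a spread that therefore cannot decide between the 2. For the liver list a smaller share stays open: 32 of 37 genes were below 1, but pah was 2.26-fold higher and fabp10a, a liver gene, had 8255 and 8416 normalized reads. An effect of BaP on either organ was not tested.

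The erythrocyte list had a median above all random lists. Splitting of reads between hemoglobin copies is argued against, since the sum over the 8 hemoglobin genes had a log2 ratio of 1.302. A larger share of red blood cell RNA may account for part of the list, with 25 of 27 genes above a ratio of 1 and 0 lower. That count cannot show share to be the whole cause, since higher expression per cell would give the same. Share alone would move the members alike only if all their RNA came from red blood cells, which was not measured. The hemoglobin genes had log2 ratios from 1.154 to 1.536. The intervals of tspo, alas2 (2.17 to 2.80) and slc4a1a (1.80 to 2.23), among the members farthest from equality, lay above them, and that of urod overlapped them. Higher heme synthesis per cell would also raise alas2 and urod, and was not tested apart from a larger share. A treatment effect remains a hypothesis, as the pattern was found and tested on the same 2 libraries.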
